A study of Homo sapiens with 24 samples.

How the data were processed

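RNA of 24 culture samples was measured on Affymetrix arrays with 54675 probe sets, 1 array per sample. Per the labels, MV4-11 cells were grown with 3 uM EPZ004777 or 0.1% DMSO for 2, 4 or 6 days and MOLM-13 cells for 6 days, with 3 biological replicates in each of 8 groups. The labels do not state how the replicates were made, or whether the days are separate cultures or the same cultures sampled again. The p-values therefore measure the spread between these samples, with no pairing across days. Total RNA was purified on columns, and biotin-labeled antisense RNA was made from it. The deposited values are one intensity per probe set and array, which the submitters' processing notes credit to GCRMA. That method adjusts background by probe sequence, quantile normalizes the arrays and summarizes each probe set, and its version is not given in the sources used here. Values were expected on the log2 scale, but the deposited intensity values ran from 4.551 to 71593 and were on a linear scale. The log2 of each was therefore taken with a pseudocount of 0, as foreseen for that case, which gives a range of 2.19 to 16.1. The lowest value was the same in all 24 arrays, so a gene near it has no measurable level, and a change from or to that level depends on the background adjustment. No pair of arrays was identical (0 pairs), and 0 columns lacked a sample.

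Of the probe sets, 41097 were listed with 1 gene symbol, 1801 with several and 11777 with none, and 62 controls were left out of the tests. Symbols were matched by Entrez ID to the RefSeq table of GRCh38.p14, which held 41043 of the 41097, with 0 symbols updated. The 19775 genes so named were filtered to those with a log2 value of at least 4 in at least 3 arrays, blind to group, and the probe set with the highest mean stood for its gene. This left 10971 genes. A further 4528 probe sets that passed the filter had no gene or several genes listed and were tested apart.

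Group means were fitted over all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over the 10971 genes of each comparison. A gene was called at an adjusted p under 0.05. The 4 comparisons of treated with vehicle cultures, 3 differences between days, 1 difference between lines and the change of vehicle cultures from day 2 to day 6 were tested. An exact test of 3 against 3 arrays cannot give a two-sided p under 0.1, so single genes were tested only in limma's model, which shares the spread across genes and groups. Of 22 gene lists fixed before the data were examined, 21 had tested members and 1 was not analysed here. The lists were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over 84 tests, and again with an estimated correlation and with fry. Overlaps were set against the number given by chance with Fisher's exact test, and correlations across genes describe genes, which are not independent replicates. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the rest.

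The filter, the tests, the lists, the alternatives and the genes to be named were chosen before the data were examined. Named genes are the 8 largest rises and 8 largest falls in each treatment comparison among called genes whose arrays do not overlap, a panel of 16 genes, up to 4 members of each list by adjusted p, and the 5 most positive and 5 most negative called genes of each difference. Of the panel, 5 genes were not tested. The text gives examples from these. The alternatives were no filter, a filter at log2 6, only the arrays of each comparison, a variance prior with trend and robust fit, the mean of a gene's probe sets or each other probe set, quantile normalization again, a common median, the replicate number as a block, each array left out, every probe set counted, and a 2-fold minimum. Alternatives chosen after the data were seen were the day 2 and day 6 vehicle arrays in place of those of day 4, and the 3' to 5' difference of each array (mean of the ACTB and GAPDH control probe sets) as a covariate.

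The steps were tested on simulated data with the same spread, with 100 genes changed by 0.5 and 100 by 1 on the log2 scale in each comparison. Of those, 75, 78, 66 and 61 and then 98, 94, 92 and 89 were recovered in the comparisons of days 2, 4 and 6 and of MOLM-13 cells, with 10, 14, 9 and 8 false calls. A simulated list shift was found, and it was the only list called (1 of 84 tests). The simulated genes varied independently, with the same spread of a gene in all groups. They had no lowest value and were not normalized, and few were changed, with as many up as down. False list calls that come from correlated genes were therefore not tested. Nor were genes near the lowest value, or the balance of higher and lower genes when many change.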

Results

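Gene expression was measured with Affymetrix arrays of 54675 probe sets in 24 culture samples of 2 human leukemia cell lines. MV4-11 is a biphenotypic B myelomonocytic leukemia line that carries the MLL-AF4 fusion, and MOLM-13 is an acute myeloid leukemia line that carries the MLL-AF9 fusion. In both, part of the histone methyltransferase MLL (KMT2A) is joined to a partner protein that draws the enzyme DOT1L to chromatin. DOT1L methylates lysine 79 of histone H3 on transcribed genes. The cells were grown with 3 uM EPZ004777, a small molecule that inhibits DOT1L, or with the vehicle, 0.1% DMSO. MV4-11 cells in IMDM medium were sampled on days 2, 4 and 6, and MOLM-13 cells in RPMI medium on day 6, with 3 biological replicates in each of the 8 groups. The question of the series is how expression changes under the inhibitor over time and in each line. All changes below are log2 fold changes of treated over vehicle cultures of the same line and day with the SE of the model, from 3 arrays per group, and levels are log2 means ± SD over 3 arrays. Each list count is given over all genes tested, and the count adjusted over the list alone is given where it differs. The number of arrays limits the precision. Across the 24 arrays the correlation with the other arrays of the group was lowest in treated MV4-11 cells on day 6, with a group mean of 0.995, and between 0.997 and 0.999 as a group mean in the other 7 groups.

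On day 2 in MV4-11 cells, genes of antigen presentation, macrophages and neutrophils were already higher under the inhibitor. HLA-DPA1, a chain of an MHC class II molecule that presents peptides to T cells, rose by 2.25 ± 0.10 (adjusted p = 1.53e-11), from a level of 7.07 ± 0.05 to 9.32 ± 0.04. RAB27B, a GTPase of vesicle secretion, rose by 2.39 ± 0.18, and ROBO1, a receptor for SLIT guidance proteins, rose by 2.34 ± 0.22. The rises of CSGALNACT1, an enzyme of chondroitin sulfate synthesis, and of ENHO, the precursor of the peptide adropin, were 2.32 ± 0.12 and 2.86 ± 0.25. CD59, CD86 and ATP1B1 completed the 8 largest rises (2.58 to 2.22), from vehicle levels near the bottom of the range of the arrays, where the size of a change depends on the background adjustment. The immediate early transcription factor EGR3 fell by 3.04 ± 0.29, the largest fall of the day (adjusted p = 6.49e-07). GPR84, a receptor for medium-chain fatty acids, fell by 1.94 ± 0.26, and the change of the amino acid oxidase IL4I1 was -1.66 ± 0.33.

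**Figure D1:**
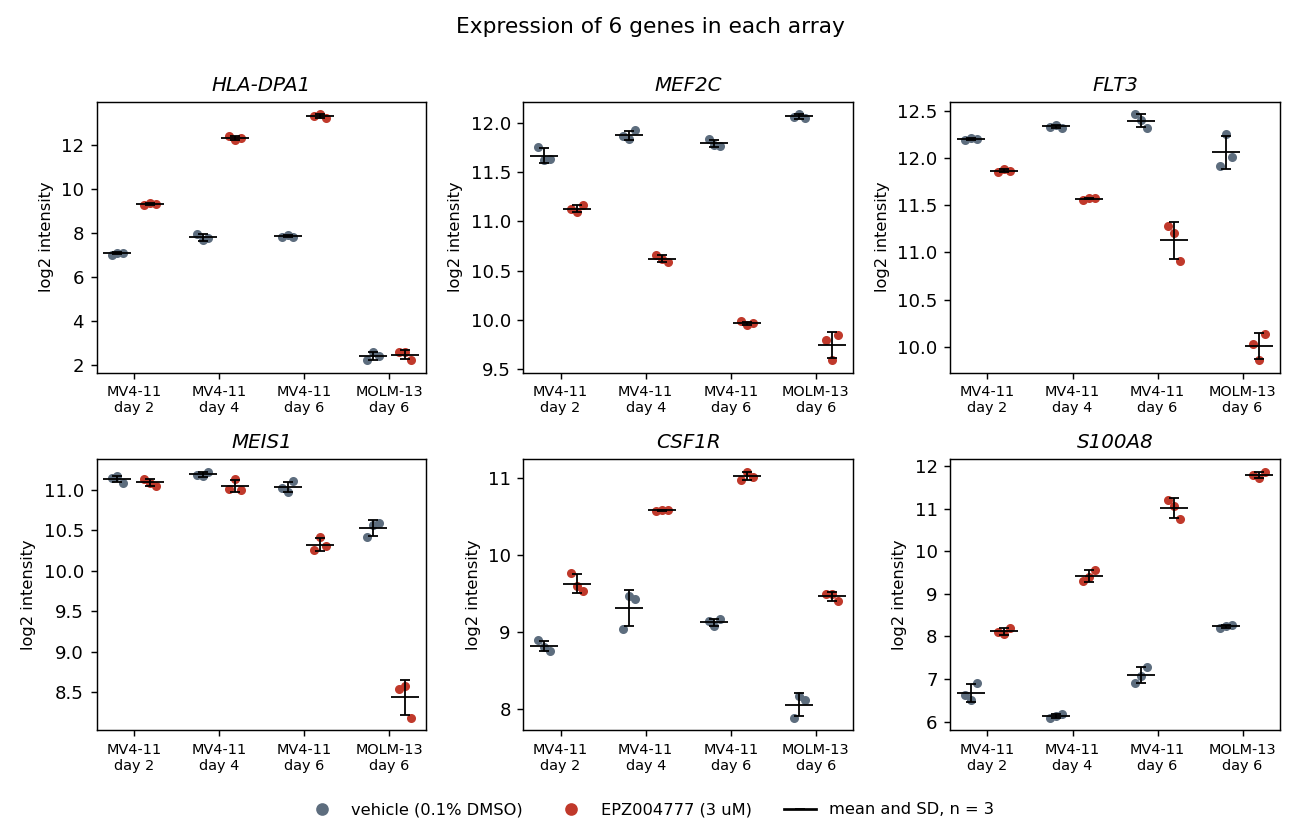
Log2 expression of 6 named genes in each of the 24 arrays, by line and day, with vehicle cultures in grey and cultures with EPZ004777 in red, and bars for the mean and SD of 3 arrays. HLA-DPA1 stands higher and MEF2C lower with each day in treated MV4-11 cells, while MEIS1 is -0.04 ± 0.08 on day 2 and -2.09 ± 0.08 in MOLM-13 cells on the log2 scale.

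In all, 1372 of 10971 genes passed on day 2 (968 higher and 404 lower), and 143 of them changed at least 2-fold (124 higher and 19 lower). Among all 10971 genes, all 3 treated arrays lay beyond all 3 vehicle arrays in 4267, where chance gives 10%, and 1355 of the 1372 were among these. The vehicle arrays of days 2 and 6, with no inhibitor, did not overlap in 2760 of all genes. An excess over 10% is therefore not particular to the inhibitor. Among MHC class II genes, 8 of 9 rose (9 when adjusted over the list alone), with a median of 1.45, as in HLA-DRA at 2.03 ± 0.18 and the invariant chain CD74 at 1.01 ± 0.09 (list adjusted p = 2.72e-15). Of 22 monocyte and macrophage genes 11 rose and 0 fell (12 and 2 when adjusted over the list alone). They included the pore-forming protein gene MPEG1 (1.10 ± 0.08), the receptor for macrophage colony-stimulating factor CSF1R (0.81 ± 0.09) and the scavenger receptor CD36 (0.90 ± 0.15), and the list median was 0.35 (adjusted p = 5.73e-06). Among neutrophil maturation genes 4 of 8 rose, among them S100A8, a subunit of calprotectin, at 1.44 ± 0.11 (list median 0.37, adjusted p = 0.00239). As the mean of their probe sets, 1 of which stood near the bottom of the range in each case, S100A8 rose by 0.72 and HLA-DPA1 by 1.39. Of the granulocyte primary granule genes 2 of 12 rose (3 when adjusted over the list alone), which were the protease genes CTSG (0.39 ± 0.07) and ELANE (0.23 ± 0.05), with a list median of 0.17 (adjusted p = 0.0229, and 0.171 with an estimated correlation). Both measured megakaryocyte and platelet genes rose, NFE2, a transcription factor, by 0.62 ± 0.10 and the integrin ITGA2B by 0.68 ± 0.17 (adjusted p = 0.00995 for the list). That list did not pass with no filter, which adds members near the bottom of the range, or when only the arrays of the comparison were fitted. The call of ITGA2B ended without treated replicate 1 (adjusted p = 0.0549) or vehicle replicate 3 (0.054).

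Stress and sterol biosynthesis genes were lower on day 2. Of the 23 amino acid and unfolded protein stress genes 13 fell and 0 rose (16 fell when adjusted over the list alone; median -0.51, adjusted p = 8.96e-12). They included the amino acid transporter SLC7A5 (-0.70 ± 0.08), asparagine synthetase ASNS (-0.62 ± 0.13) and the pseudokinase TRIB3 (-1.45 ± 0.28). Of the 18 sterol biosynthesis genes 8 fell and 0 rose (10 fell when adjusted over the list alone; median -0.34, adjusted p = 1.8e-07), such as farnesyl diphosphate synthase FDPS (-0.36 ± 0.07). In the S-adenosylmethionine cycle, which supplies the methyl donor of DOT1L, 1 of 15 genes fell, which was CBS, the first enzyme of transsulfuration, at -1.02 ± 0.14. The list median was -0.07 (adjusted p = 0.0365, and 0.0789 with an estimated correlation), and the call of the list ended without treated replicate 2 (adjusted p = 0.0658) or vehicle replicate 1 (0.0641), when only the arrays of the comparison were fitted, with the mean of probe sets, or with quantile normalization again. Of the 25 MLL-fusion target genes listed 17 were tested, and 1 of these rose and 4 fell (1 and 6 when adjusted over the list alone; median -0.07, adjusted p = 0.0031). The transcription factors MEF2C and PBX3 fell, at -0.54 ± 0.06 and -0.44 ± 0.07, and MEIS1 was at -0.04 ± 0.08 (adjusted p = 0.831). The receptor tyrosine kinase FLT3 fell by 0.33 ± 0.09 (adjusted p = 0.0163), with adjusted p = 0.0524 without treated replicate 1 and 0.0513 without vehicle replicate 2. Of 40 cell cycle genes 0 rose and 1 fell (0 when adjusted over the list alone; median -0.05, adjusted p = 0.006, and 0.144 with an estimated correlation). None of 21 MYC and ribosome biogenesis genes passed alone or over the list (median -0.14, adjusted p = 0.00423 for the list, and 0.12 with an estimated correlation), and MYC itself was at 0.08 ± 0.12 (adjusted p = 0.763).

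The remaining 10 lists did not pass on day 2. Their medians ranged from -0.29 for inflammatory cytokine and chemokine genes (2 of 14 rose and 2 fell, or 3 fell when adjusted over the list alone, adjusted p = 0.17), among them tumor necrosis factor TNF at -1.21 ± 0.21, to 0.57 for B-lymphoid markers (3 of 5 rose and 1 fell, adjusted p = 0.167). The medians were -0.07 for DOT1L and elongation complex genes (1 of 20 rose and 2 fell, adjusted p = 0.094), -0.07 for erythroid markers (1 of 4 fell, adjusted p = 0.266) and 0.24 for T and NK cell markers (2 of 3 rose, adjusted p = 0.0918). The other five had medians between -0.01 and 0.04. They were apoptosis genes (2 of 19 rose and 1 fell, adjusted p = 0.719), p53 targets (3 of 21 rose and 2 fell, or 3 and 3 when adjusted over the list alone, adjusted p = 0.735), interferon-stimulated genes (0 of 22 passed, adjusted p = 0.852), stem and progenitor genes (2 of 11 rose, or 3 when adjusted over the list alone, adjusted p = 0.459) and housekeeping genes (0 of 14 passed, adjusted p = 0.595). In these 5 lists the median, the mean and the direction of the test did not share a sign. DOT1L itself fell by 0.55 ± 0.13 (adjusted p = 0.00931), a call that ended with the mean of its probe sets in place of the highest (adjusted p = 0.0547). The count of 1372 fell to 909 without vehicle replicate 1. Among the 8 largest falls, CHAC1 (-1.47 ± 0.44, adjusted p = 0.0330) lost its call without any 1 of its 6 arrays (adjusted p from 0.0567 to 0.106) or with no filter (0.0882). RHOB (-1.54 ± 0.39) lost its call without treated replicate 3 (-0.90, adjusted p = 0.0761) or vehicle replicate 2 (0.0505), or when only the arrays of the comparison were fitted (0.121).

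On day 4 in MV4-11 cells the MHC class II genes rose further, and another set of genes fell that stood high in the day 4 vehicle cultures. HLA-DPA1 rose by 4.52 ± 0.10 to a level of 12.31 ± 0.10 (adjusted p = 5.02e-17) and HLA-DPB1, its partner chain, by 5.08 ± 0.24. F13A1, a coagulation factor subunit of monocytes and platelets, rose by 4.56 ± 0.19, and ROBO1 and RAB27B by 4.46 ± 0.22 and 4.18 ± 0.18. TSPOAP1, GASK1B and ENHO (5.14, 4.54 and 4.18) rose from vehicle levels near the bottom of the range. The antiviral gene IFIT3 fell by 7.07 ± 1.07 (adjusted p = 1.99e-05) from 9.58 ± 0.36 in vehicle cultures to the bottom of the range. The immediate early gene EGR1 fell by 5.56 ± 0.46, and the change of the stress transcription factor ATF3 was -5.23 ± 0.46.

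Of 22 interferon-stimulated genes 20 fell and 0 rose on day 4 (median -2.14, adjusted p = 3.29e-10, and 0.174 with an estimated correlation), such as ISG15 at -2.37 ± 0.20 and IFI44L at -4.23 ± 0.28. Their median level per array was 7.77 to 8.55 in the day 4 vehicle cultures, 5.37 to 5.49 in the day 4 treated cultures and 4.19 to 5.36 in the day 2 vehicle cultures. In the 3 day 6 vehicle cultures it was 7.27, 5.38 and 4.19. With the day 2 and day 6 vehicle cultures in place of those of day 4, a comparison added after the data were seen, the list median was 0.05. The interferon-induced chemokine CXCL10 then stood at -0.72 (adjusted p = 0.174), IFIT1 at -1.30 (0.182) and IFI44L at -0.27 (0.365), none of them called, while IFIT3 stood at -2.97, ISG15 at -0.55 and ATF3 at -2.20, all called. Inflammatory cytokine and chemokine genes were lower as a list (2 of 14 rose and 9 fell, median -1.77, adjusted p = 0.000333, and 0.105 with an estimated correlation), with TNF at -3.67 ± 0.21 and the chemokine CCL5 at -3.09 ± 0.23. That list did not pass with the other vehicle cultures (median -0.35, adjusted p = 0.374), where CCL5 was at -1.85. Its members and those of the stress list were also among the genes that were higher in day 4 vehicle cultures than in day 2 and day 6 vehicle cultures (9 of 14 and 13 of 23).

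**Figure D2:**
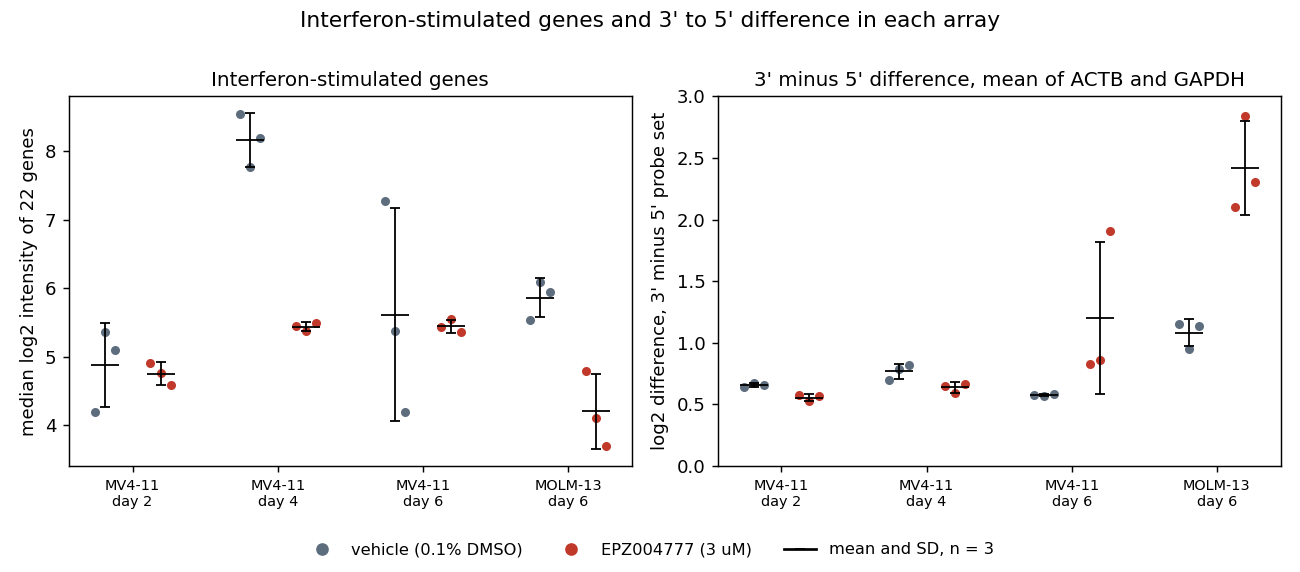
Median log2 expression of 22 interferon-stimulated genes (left) and mean 3' minus 5' log2 difference of the ACTB and GAPDH control probe sets (right) in each of the 24 arrays, by group. The interferon-stimulated genes stand at 7.77 to 8.55 in the day 4 vehicle arrays, and the 3' to 5' difference is widest in treated MOLM-13 cells, with a mean of 2.42.

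On day 4 all 9 MHC class II genes rose (median 3.14, adjusted p = 1.14e-10), with HLA-DRA at 4.17 ± 0.18 and CD74 at 2.06 ± 0.09. Of the 40 cell cycle genes 33 fell and 0 rose (34 fell when adjusted over the list alone; median -0.38, adjusted p = 3.63e-11). CDC6, which loads replication helicases, fell by 1.10 ± 0.08, and the proliferation marker MKI67 was at -0.76 ± 0.07. With the other vehicle cultures the cell cycle median was -0.61. Sterol biosynthesis genes fell in 17 of 18 cases (median -1.42, adjusted p = 2.13e-13), with DHCR7, the last enzyme of cholesterol synthesis, at -3.19 ± 0.14. Stress genes fell in 22 of 23 cases (median -1.21, adjusted p = 1.01e-12), with TRIB3 at -4.49 ± 0.28. The stress median was -0.81 and TRIB3 was at -2.63 with the other vehicle cultures, where the list still passed (adjusted p = 1.05e-06) but not with an estimated correlation (0.127), and the sterol median was -1.12. Among granule genes 8 of 12 rose and 0 fell (median 0.40, adjusted p = 0.000837, and 0.0627 with an estimated correlation), with CTSG at 1.82 ± 0.07 and the peroxidase MPO at 1.08 ± 0.20. Among neutrophil maturation genes 4 of 8 rose (median 0.55, adjusted p = 0.012, and 0.0595 with an estimated correlation), with S100A8 at 3.28 ± 0.11 and CSF3R, the receptor for granulocyte colony-stimulating factor, at 1.25 ± 0.08. Both megakaryocyte and platelet genes rose (median 1.37, adjusted p = 0.0289, and 0.0789 with an estimated correlation), with NFE2 at 2.02 ± 0.10. With no filter neither this list nor the neutrophil list passed on day 4, and this list did not pass when only the arrays of the comparison were fitted.

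In all, 5068 genes passed on day 4 (2763 higher and 2305 lower), 768 of them at least 2-fold (463 higher and 305 lower), and the arrays of the 2 groups did not overlap in 6482 of all genes (10% by chance), 4900 of the 5068 among them. With a common median for each array 2515 were higher and 2559 lower. Lists that did not pass included the monocyte and macrophage genes (11 of 22 rose and 6 fell, median 0.33, adjusted p = 0.212). That list passed with the other vehicle cultures (13 rose and 2 fell, median 0.39, adjusted p = 0.00118, and 0.0687 with an estimated correlation). With those of day 4 CSF1R rose by 1.27 ± 0.09, while NCF1, a subunit of the phagocyte NADPH oxidase, fell by 3.06 ± 0.18 and the integrin ITGAM was at 0.42 ± 0.29 (adjusted p = 0.254). With the other vehicle cultures ITGAM stood at 2.16 (adjusted p = 4.39e-07) and NCF1 at -1.81. The MLL-fusion target genes did not pass as a list (2 of 17 rose and 7 fell, median -0.15, adjusted p = 0.0694), but did with no filter or without vehicle replicate 1 (adjusted p = 0.0327), and MEF2C, FLT3 and PBX3 fell, at -1.25 ± 0.06, -0.77 ± 0.09 and -0.72 ± 0.07. MEIS1 was at -0.15 ± 0.08 (adjusted p = 0.157) and MYC at 0.21 ± 0.12 (adjusted p = 0.160, from 0.00925 to 0.36 over the alternatives). DOT1L fell by 0.99 ± 0.13. Stem and progenitor genes went both ways (4 of 11 rose and 3 fell, median 0.00 and mean 0.13, adjusted p = 0.739), with the receptor KIT up by 2.49 ± 0.10 and CD38, an ectoenzyme of maturing blood cells, at -1.48 ± 0.12. The p53 targets (6 of 21 rose and 9 fell, median -0.17, adjusted p = 0.119) included the cell cycle inhibitor CDKN1A at -1.69 ± 0.10. The S-adenosylmethionine cycle genes (1 of 15 rose and 5 fell) had a median of -0.05 (adjusted p = 0.101), but with the other vehicle cultures 0 rose and 9 fell and the list passed (median -0.26, adjusted p = 0.00974, and 0.0386 with an estimated correlation).

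The other seven lists of day 4 did not pass either. The DOT1L and elongation complex genes (2 of 20 rose and 6 fell, adjusted p = 0.247) and the apoptosis genes (3 of 19 rose and 6 fell, adjusted p = 0.333) both had a median of -0.09. MYC and ribosome biogenesis genes (3 of 21 rose and 5 fell, or 2 and 5 when adjusted over the list alone) had a median of -0.11 (adjusted p = 0.266), and of -0.32 with the other vehicle cultures, where the list passed (adjusted p = 0.00118, and 0.0856 with an estimated correlation). B-lymphoid markers (2 of 5 rose and 2 fell, adjusted p = 0.442) had a median of -0.11 and a mean of 0.66, with IGLL1, a surrogate light chain of pre-B cells, at 1.87 ± 0.15, or at 1.00 with the other vehicle cultures. The T and NK cell markers (2 of 3 rose) had a median of 0.40 (adjusted p = 0.174), the erythroid markers (1 of 4 fell, or 2 when adjusted over the list alone) one of -0.21 (adjusted p = 0.243) and the housekeeping genes (1 of 14 rose and 3 fell) one of -0.02 (adjusted p = 0.329).

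On day 6 in MV4-11 cells all 9 MHC class II genes rose and 39 of 40 cell cycle genes fell. HLA-DPB1 rose by 6.07 ± 0.24 (adjusted p = 9.04e-14), from 5.63 ± 0.28 to 11.70 ± 0.19, and HLA-DPA1 by 5.46 ± 0.10. S100A8 rose by 3.92 ± 0.11, CSF1R by 1.90 ± 0.09 and TMEM176B, a membrane protein of myeloid cells, by 5.17 ± 0.21. The MLL-fusion targets MEF2C, FLT3, PBX3 and MEIS1 fell, at -1.82 ± 0.06, -1.27 ± 0.09, -1.04 ± 0.07 and -0.71 ± 0.08. EGR1 fell by 4.82 ± 0.46, and TNF was at -3.84 ± 0.21. GASK1B, ZNF366, TSPOAP1 and CRISPLD2 rose by 5.21 to 5.84 from vehicle levels near the bottom of the range, and IL4I1, EGR3, MIR210HG, AKR1C2 and GPR84 fell to that level, with changes from -5.03 to -3.84. Treated replicate 3 stood apart, with 3' minus 5' differences of 2.80 for ACTB and 1.03 for GAPDH, against 0.954 to 1.49 and 0.0445 to 0.278 in the other 17 MV4-11 arrays. The mean of the 2 differences was also wider in treated replicates 1 and 2, at 0.826 and 0.861, than in the 3 vehicle arrays of the day, at 0.567 to 0.583.

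All 9 MHC class II genes rose on day 6 (median 3.57, adjusted p = 4.29e-08), with HLA-DQB1 at 4.19 ± 0.18 and CD74 at 2.20 ± 0.09. Of 22 monocyte and macrophage genes 14 rose and 2 fell (median 0.60, adjusted p = 0.00423, and 0.105 with an estimated correlation), with MPEG1 at 1.58 ± 0.08 and the immune receptor CD300LF at 0.96 ± 0.07. Among neutrophil maturation genes 6 of 8 rose and 1 fell (median 0.83, adjusted p = 0.0171, and 0.0709 with an estimated correlation), with S100A9, the partner of S100A8, at 2.14 ± 0.19. The neutrophil list did not pass with no filter or when only the arrays of the comparison were fitted. Of the granule genes 8 of 12 rose and 0 fell (median 0.61, adjusted p = 0.00367, and 0.104 with an estimated correlation), with CTSG at 1.89 ± 0.07 and ELANE at 1.11 ± 0.05. In the cell cycle list 39 of 40 fell (median -0.83, adjusted p = 9.02e-18), with CDC6 at -1.63 ± 0.08, the mitotic kinase PLK1 at -1.62 ± 0.09 and MKI67 at -1.48 ± 0.07. Of the p53 targets 3 of 21 rose and 12 fell (median -0.49, adjusted p = 0.00634), with CDKN1A at -2.17 ± 0.10, the death receptor FAS at -2.40 ± 0.19 and TP53INP1, a stress-induced regulator of autophagy, up by 1.42 ± 0.08. Of MYC and ribosome biogenesis genes 11 of 21 fell (10 when adjusted over the list alone; median -0.21, adjusted p = 0.00239, and 0.105 with an estimated correlation). The lactate dehydrogenase LDHA fell by 0.72 ± 0.06. MYC fell by 0.49 ± 0.12 (adjusted p = 0.00115), with adjusted p = 0.0826 when only the arrays of the comparison were fitted, and its value was -0.27 without treated replicate 3 and -0.16 with the 3' to 5' difference of each array as a covariate.

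Sterol biosynthesis genes fell in 16 of 18 cases on day 6 (median -1.43, adjusted p = 3.18e-09), with DHCR7 at -3.57 ± 0.14 and the sterol isomerase EBP at -1.66 ± 0.09. Of the stress genes 1 of 23 rose and 19 fell (20 when adjusted over the list alone; median -0.74, adjusted p = 1.1e-05, and 0.166 with an estimated correlation), with TRIB3 at -2.89 ± 0.28 and the unfolded protein response factor XBP1 at -1.63 ± 0.12. In the S-adenosylmethionine cycle 10 of 15 fell (11 when adjusted over the list alone; median -0.28, adjusted p = 0.0056), with CBS at -1.78 ± 0.14 and the folate enzyme MTHFD1 at -0.56 ± 0.06. The MLL-fusion target genes did not pass as a list (2 of 17 rose and 6 fell, median -0.07, adjusted p = 0.0714), but did with that covariate (median -0.15, adjusted p = 0.0108) or without treated replicate 3 (-0.13, 0.0339), and with no filter or the mean of probe sets. Apoptosis genes went both ways (6 of 19 rose and 5 fell, median 0.07 and mean -0.05, adjusted p = 0.934), with the death-promoting BCL2 relative BMF up by 1.59 ± 0.11. Of the interferon-stimulated genes 7 of 22 rose and 4 fell (3 when adjusted over the list alone; median -0.22, adjusted p = 0.773), while their median level in the 3 day 6 vehicle arrays was 7.27, 5.38 and 4.19. IFIT3 fell by 3.76 ± 1.07 (adjusted p = 0.00485) with a vehicle level of 6.01 ± 3.47, was at -2.01 without vehicle replicate 1, and was not called when only the arrays of the comparison were fitted (adjusted p = 0.117). Inflammatory genes (4 of 14 rose and 7 fell, median -0.67, adjusted p = 0.212) included the cytokine IL18, up by 1.99 ± 0.19.

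For the other lists of day 6 the medians lay between -0.32 and 1.49. DOT1L and elongation complex genes (3 of 20 rose and 8 fell, median -0.06, adjusted p = 0.288) included DOT1L at -0.36 ± 0.13 (adjusted p = 0.0236). Its call ended without treated replicate 1 (adjusted p = 0.12), treated replicate 2 (0.143), vehicle replicate 1 (0.0654) or vehicle replicate 3 (0.057), when only the arrays of the comparison were fitted (0.164) or with no filter (0.0526). Without treated replicate 3 DOT1L was at -0.58. Stem and progenitor genes (4 of 11 rose and 4 fell, median -0.06, adjusted p = 0.911) included KIT at 2.12 ± 0.10 and CD38 at -2.39 ± 0.12. The B-lymphoid (2 of 5 rose, median 0.20, adjusted p = 0.32), T and NK cell (2 of 3 rose, median 0.29, adjusted p = 0.224), erythroid (2 of 4 fell, median -0.32, adjusted p = 0.212) and megakaryocyte and platelet markers (2 of 2 rose, median 1.49, adjusted p = 0.0566) did not pass, though the last did with the mean of probe sets, with a common median or without treated replicate 2 (adjusted p = 0.0359). Nor did the housekeeping genes (7 of 14 fell, median -0.12, adjusted p = 0.0671), which passed with no filter, with only the arrays of the comparison, with a common median and with a variance prior with trend. In all, 6800 genes passed (3688 higher and 3112 lower), 1281 of them at least 2-fold (859 higher and 422 lower), and arrays did not overlap in 7107 of all genes (10% by chance), 6409 of the 6800 among them. The balance turned with a common median for each array (3176 higher and 3707 lower) and with the mean of probe sets (3241 higher and 3653 lower). With the 3' to 5' covariate, added after the data were seen, 5508 of the 6800 were still called in the same direction.

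**Figure D3:**
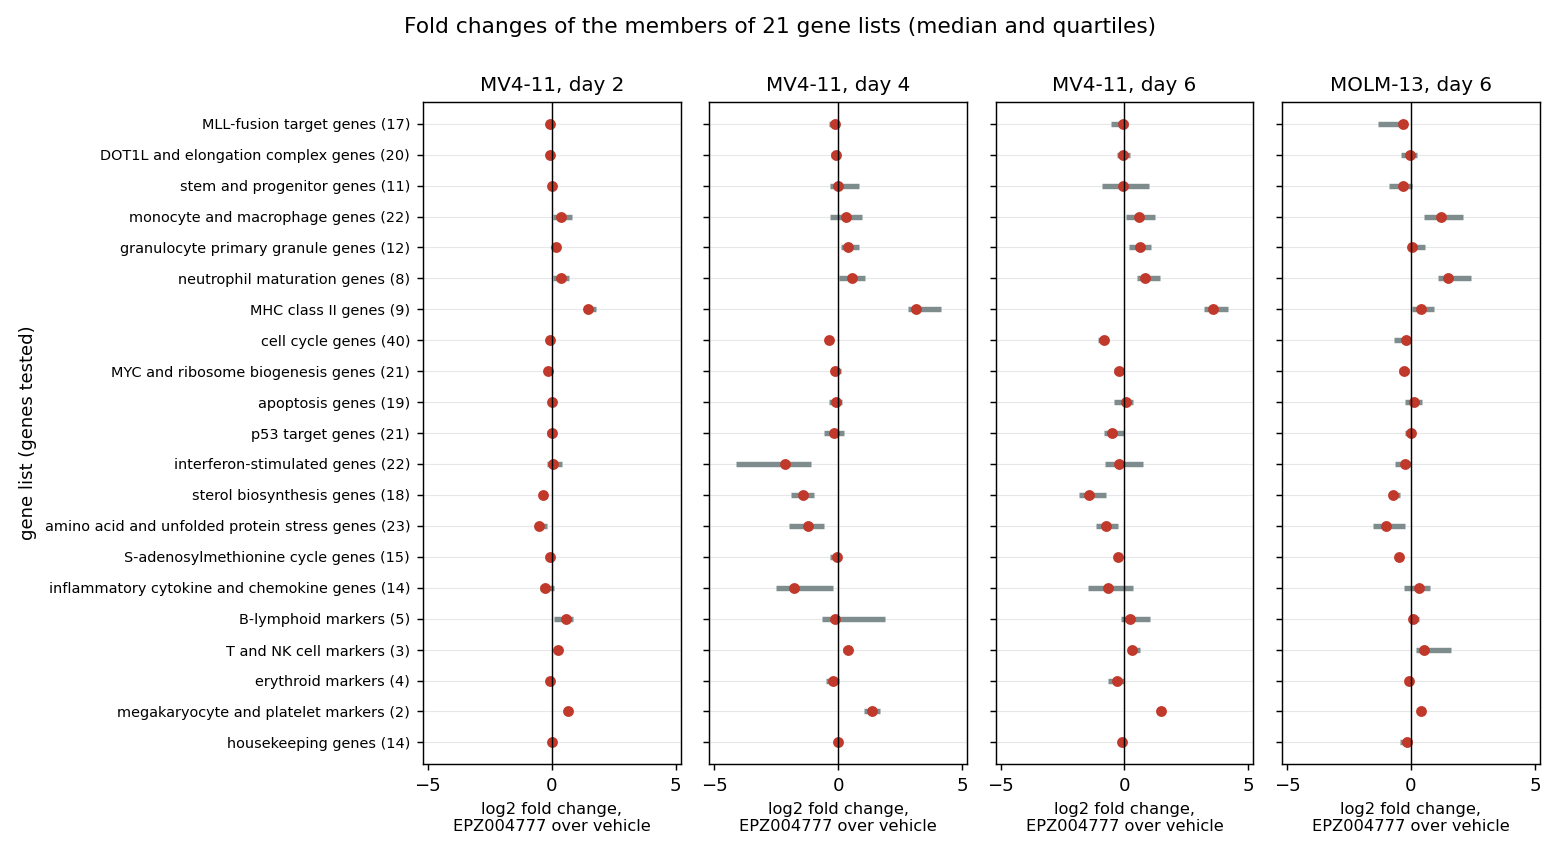
Log2 fold changes of the 21 gene lists tested in the 4 comparisons of treated with vehicle cultures, with the median of each list as a point and its quartiles as a bar. The MHC class II median goes from 1.45 on day 2 to 3.57 on day 6 in MV4-11 cells and is 0.42 in MOLM-13 cells.

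In MOLM-13 cells on day 6, genes of monocytes and neutrophils rose and MLL-fusion target genes fell. S100A9 rose by 4.04 ± 0.19, SLPI, an inhibitor of neutrophil elastase, by 5.57 ± 0.23 and the chemokine CXCL8 by 4.12 ± 0.27. MEIS1 fell by 2.09 ± 0.08 (adjusted p = 6.48e-14), and the changes of MEF2C and FLT3 were -2.32 ± 0.06 and -2.05 ± 0.09. ANPEP, the surface aminopeptidase CD13, rose by 6.57, the lipoxygenase ALOX5 by 6.22 and CD14, a coreceptor for bacterial lipopolysaccharide, by 2.23, all from vehicle levels near the bottom of the range. The homeobox gene HMX2, EGR1 and IL12RB2, a chain of an interleukin receptor, fell, at -4.79 ± 0.11, -4.65 ± 0.46 and -4.17 ± 0.27. DYNC1I1, an intermediate chain of the motor dynein, fell by 6.50 to the bottom of the range. The 3' minus 5' difference of the control probe sets was wider in the treated MOLM-13 arrays, at 2.42 ± 0.38, than in the vehicle arrays, at 1.08 ± 0.11 (mean ± SD, n = 3).

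Of 22 monocyte and macrophage genes 18 rose and 1 fell in MOLM-13 cells (median 1.21, adjusted p = 3.95e-08). CYBB, the catalytic subunit of the phagocyte NADPH oxidase, rose by 4.07 ± 0.16, MPEG1 by 2.16 ± 0.08 and CSF1R by 1.41 ± 0.09. Among neutrophil maturation genes 7 of 8 rose (median 1.52, adjusted p = 1.36e-05), with S100A8 at 3.55 ± 0.11 and the nuclear protein MNDA at 1.37 ± 0.08. Of 17 MLL-fusion target genes 12 fell and 0 rose (median -0.32, adjusted p = 0.00143), with the cyclin-dependent kinase CDK6 at -1.32 ± 0.06 beside MEIS1, MEF2C and FLT3, while PBX3 was at -0.10 ± 0.07 (adjusted p = 0.227). Of the cell cycle genes 2 of 40 rose and 23 fell (median -0.21, adjusted p = 0.00423, and 0.135 with an estimated correlation), with CDC6 at -1.04 ± 0.08. MYC and ribosome biogenesis genes fell in 14 of 21 cases (median -0.26, adjusted p = 0.012, and 0.166 with an estimated correlation), with the level of MYC itself at 13.50 ± 0.02 in vehicle and 12.50 ± 0.14 in treated cultures. Sterol genes fell in 14 of 18 cases (median -0.71, adjusted p = 0.00239, and 0.186 with an estimated correlation), with FDPS at -0.60 ± 0.07. Stress genes fell in 19 of 23 cases (median -1.02, adjusted p = 0.000195, and 0.222 with an estimated correlation), with the serine synthesis enzyme PSAT1 at -1.51 ± 0.11. In the S-adenosylmethionine cycle 1 of 15 rose and 13 fell (median -0.47, adjusted p = 0.00654), with MAT2B, a regulator of S-adenosylmethionine synthesis, at -1.17 ± 0.11 and CBS at -1.34 ± 0.14.

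The other lists of MOLM-13 cells did not pass. MHC class II genes (4 of 9 rose and 1 fell, median 0.42, adjusted p = 0.0673), which passed without treated replicate 3 (adjusted p = 0.0434) or vehicle replicate 2 (0.031), included CD74 at 1.11 ± 0.09, though another probe set of CD74 gave -0.05. Granule genes (5 of 12 rose and 3 fell, median 0.05, adjusted p = 0.233) included MPO, up by 2.34 ± 0.20 from 11.24 ± 0.13 to 13.57 ± 0.06. Inflammatory genes (5 of 14 rose and 3 fell, or 4 and 3 when adjusted over the list alone; median 0.31, adjusted p = 0.229) included CXCL8, and stem and progenitor genes (6 of 11 fell) had a median of -0.33 (adjusted p = 0.273). Interferon-stimulated genes (3 of 22 rose and 7 fell, median -0.22 and mean -0.55, adjusted p = 0.815) included MX2, which rose by 1.90 ± 0.26 while more members fell. Their median level per array was 3.70 to 4.79 in treated and 5.54 to 6.09 in vehicle cultures. Apoptosis genes (7 of 19 rose and 5 fell, median 0.12, adjusted p = 0.273) and p53 targets (5 of 21 rose and 5 fell, median 0.00 and mean -0.08, adjusted p = 0.924) went both ways. B-lymphoid markers (1 of 5 rose and 1 fell, median 0.09 and mean -0.51, adjusted p = 0.911) included IGLL1 at -3.67 ± 0.15. The DOT1L and elongation complex genes (5 of 20 rose and 8 fell, median -0.04, adjusted p = 0.792) included DOT1L at -0.09 ± 0.13 (adjusted p = 0.576), for which another probe set gave 0.51. The T and NK cell (2 of 3 rose, median 0.51, adjusted p = 0.248), erythroid (0 of 4 passed, median -0.06, adjusted p = 0.942) and megakaryocyte and platelet markers (1 of 2 rose, median 0.41, adjusted p = 0.3) and the housekeeping genes (3 of 14 rose and 7 fell, median -0.14, adjusted p = 0.321) completed the lists.

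In all, 7214 genes passed in MOLM-13 cells (3211 higher and 4003 lower), 1400 of them at least 2-fold (608 higher and 792 lower), and arrays did not overlap in 7492 of all genes (10% by chance), 6833 of the 7214 among them. The balance turned with a common median for each array (3846 higher and 3450 lower) and with quantile normalization again (3828 higher and 3378 lower). With the 3' to 5' difference of each array as a covariate the count was 4339, and 3677 of the 7214 genes, or 1173 of the 1400 with a 2-fold change, were still called in the same direction. Treated and vehicle arrays of this line do not overlap in that difference, so values with the covariate rest on a slope fitted within groups. With that covariate the MLL-fusion target median was -0.89 and DOT1L was lower (-0.78, adjusted p = 0.00112). MYC was then at -0.29, CDC6 at -0.67 and MAT2B at -0.56, all still called. ITGAM, which had risen by 1.21 ± 0.29, was then not called (adjusted p = 0.141). The MHC class II list passed with it (adjusted p = 0.00753), as did the granule list (adjusted p = 0.0126).

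In MV4-11 cells the effect on MHC class II and cell cycle genes was larger on day 6 than on day 2. From day 2 to day 6 the effect of the inhibitor changed for 4343 genes (2294 more positive and 2049 more negative, but 1962 and 2405 with a common median for each array and 1934 and 2512 with the mean of probe sets). With the 3' to 5' difference of each array as a covariate, 2960 of the 4343 were still called in the same direction. For the transcription factor ZNF366 the effect rose by 5.63 ± 0.22, for GASK1B by 5.21 ± 0.21, and for the lipid enzymes ALOX5 and GPAT3 by 4.85 ± 0.16 and 4.71 ± 0.19. It became more negative for EGR1 (-3.38 ± 0.65), IL4I1 (-3.37 ± 0.47) and DHCR7 (-3.01 ± 0.20). Between these days the MHC class II list moved up by a median of 1.92 (adjusted p = 1.56e-08) and the cell cycle list moved by -0.78 (adjusted p = 2.54e-22), with 39 of 40 members more negative. Of the genes called on day 2, 876 were also higher on day 6, against 325.4 given by chance, and 342 were also lower, against 114.6, while 27 went the opposite way. Fisher's exact test gave p of at most 3.63e-128 in each direction for each of the 3 pairs compared. Within a pair the comparisons share no arrays, but each pair holds the day 6 comparison of MV4-11 cells. The test counts genes as independent, and all comparisons share the estimated spread of each gene, so these p-values do not measure agreement between separate experiments. Across genes, which are not independent replicates, the log2 fold changes of days 2 and 6 had r = 0.70 and rho = 0.61.

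Day 4 differed from both other days in genes that stood high in its vehicle cultures. From day 2 to day 4 the effect changed for 1644 genes (792 more positive and 852 more negative), and for 3540 with the day 2 and day 6 vehicle cultures in place of those of day 4. It became more positive for TSPOAP1 (4.08 ± 0.30), HLA-DPB1 (3.31 ± 0.34) and the iron exporter SLC40A1 (3.23 ± 0.15), and more negative for CXCL10 (-6.05 ± 0.72), IFIT1 (-5.61 ± 1.33), IFI44 (-4.42 ± 0.61) and KCNE1 (-4.63 ± 0.74). With the other vehicle cultures those of CXCL10, IFIT1, IFI44 and KCNE1 were -0.40, -0.71, -0.39 and -0.94, and none was called. From day 4 to day 6 the effect changed for 2824 genes (1522 more positive and 1302 more negative, but 1263 and 1710 with a common median for each array and 1253 and 1817 with the mean of probe sets), or for 1497 with the 3' to 5' difference as a covariate. With that covariate 1245 of the 2824 were still called in the same direction. The heme-degrading enzyme HMOX1 moved by 5.55 ± 0.30, or by 2.33 with the other vehicle cultures, and the adaptor subunit AP1S3 by -2.15 ± 0.38, or by -1.20. CXCL10 and the antiviral GTPase MX1 moved by 5.39 ± 0.72 and 4.16 ± 0.92, but by -0.25 and -0.35 with the other vehicle cultures. Days 4 and 6 shared 2251 higher genes (928.81 given by chance) and 1659 lower genes (653.83 given by chance), with 115 opposite and r = 0.79 across genes.

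The lines differed in the size of the effect for 5709 genes on day 6 (2123 more positive in MOLM-13 cells and 3586 more negative). With a common median for each array the balance turned, at 3201 more positive and 2597 more negative. The microtubule-associated gene NAV3 was more positive in MOLM-13 cells by 6.07 ± 0.12, and the transcription factor ZEB1 by 5.42 ± 0.10. The effect was more negative for ROBO1 (-5.71 ± 0.31), HLA-DPB1 (-5.66 ± 0.34) and DYNC1I1 (-6.58 ± 0.19). A gene near the bottom of the range in either line can differ in this way without a different response. That was checked only for MHC class II genes. The MHC class II list differed by a median of -2.65 (adjusted p = 1.12e-06), with 9 of 9 members more negative. The 5 members that were above the filter level in all 6 MOLM-13 arrays each had a more negative effect than in MV4-11 cells, with differences from -1.08 for CD74 to -5.66 for HLA-DPB1. Cell cycle genes were less reduced in MOLM-13 cells (27 of 40 more positive, median 0.61, adjusted p = 3.43e-11), and so were p53 targets (11 of 21 more positive and 3 more negative, median 0.43, adjusted p = 0.0124). The lines shared 1837 higher genes (1079.4 given by chance) and 2057 lower genes (1135.5 given by chance), and 851 genes called in both went opposite ways, with r = 0.44 and rho = 0.50 across genes. With the 3' to 5' difference as a covariate the genes called the same way in both lines went from 3894 to 2286. Of the 5709 genes that differed between lines, 4650 were still called in the same direction with it. The median difference over all genes was -0.10, and 0.06 when each array was shifted to a common median. The lines also differ in medium and in fusion partner, and no group separates these.

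Between days 2 and 6 of the vehicle cultures of MV4-11 cells, 123 genes passed (86 higher and 37 lower), 6 of them at least 2-fold. Arrays of these days did not overlap in 2760 of all genes (10% by chance), 121 of the 123 among them. The count was 59, 45 and 79 without vehicle replicates 1, 2 and 3 of day 2, and 28, 43 and 366 without vehicle replicates 1, 2 and 3 of day 6. When only these 6 arrays were fitted the count was 4.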

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

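Of the tests in this part, those chosen after the results were seen are the day 4 vehicle level, the 3' to 5' covariate and the inhibitor's own effect on interferon-stimulated genes, the RNA quality of treated replicate 3 and both tests of the 3' to 5' covariate in MOLM-13 cells.

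Interferon-stimulated genes were lower under the inhibitor on day 4 in MV4-11 cells, while the day 4 vehicle cultures stood 2.52 above the day 2 and day 6 vehicle cultures as a median of the 22 genes. With the 3' to 5' difference of each array as a covariate, 20 of the 20 members called lower were still called lower (median from -2.59 to -2.56). The mean difference was 0.637 in the treated and 0.767 in the vehicle arrays of that day, so the covariate could move these values little. The count therefore does not decide on lower RNA quality in the day 4 vehicle arrays as the whole cause. The mean differences of the day 4 vehicle arrays, 1.28 for ACTB and 0.256 for GAPDH, lay inside the range of the other 21 arrays, a bound set before the result was seen, but that range was set by treated MOLM-13 arrays. They lay above the day 2 and day 6 vehicle arrays (1.07 to 1.13 and 0.0445 to 0.229), so a part played by RNA quality is not excluded by them. A lowering of the list below its level in the day 2 and day 6 vehicle cultures is argued against. Only 3 members (IFIT3, ISG15 and USP18) were called lower in day 4 treated cultures than in those vehicle cultures, and 9 were called higher. A raised level in the vehicle cultures of that day may therefore account for most of the difference, since the same treated cultures differed by a median of 0.05 from the other vehicle cultures. Whether the inhibitor lowered or prevented the same rise in treated cultures stays open. Each day has vehicle samples of its own, and the labels do not state whether these are separate cultures or the same cultures sampled again. No group separates the day from the cultures. The median level of the list was at most 5.55 in treated MV4-11 arrays of any day, and 7.27, 5.38 and 4.19 in the 3 day 6 vehicle arrays. In MOLM-13 cells the list level was 3.70 to 4.79 in treated and 5.54 to 6.09 in vehicle arrays.

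Replicate 3 of treated MV4-11 cells on day 6 stood apart from its group, with 1.70% of genes at least 2-fold from the mean of the other replicates, against 0.438% and 0.419% for replicates 1 and 2. RNA of MOLM-13 cells in that sample is argued against by a median level of 2.19 over 7 genes that stood high in MOLM-13 arrays and near the bottom of the range in the other MV4-11 arrays. Lower RNA quality may be the source, with 3' minus 5' differences of 2.80 for ACTB and 1.03 for GAPDH, both above the other 17 MV4-11 arrays. The bound set before the result was seen took in the treated MOLM-13 arrays too, and by it the value was not out of range. It was set again because those arrays have wide differences of their own, and a culture further along the same response stays open (r = 0.0213 across genes).

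Treated MOLM-13 arrays had the wider 3' to 5' difference (2.42 ± 0.38 against 1.08 ± 0.11, n = 3), so RNA quality moves with the treatment there. It does on day 6 in MV4-11 cells too (0.826, 0.861 and 1.91 against 0.567 to 0.583), where 5508 of 6800 genes were still called in the same direction with the covariate. In MOLM-13 cells 3677 of 7214 genes were still called in the same direction with the difference as a covariate, while 31 were called in the opposite direction. The slope of the covariate comes from the spread within groups. The SD of the difference was 0.616 in treated MV4-11 cells on day 6 and 0.381 in treated MOLM-13 cells, against 0.00808 to 0.11 in the other groups. Treated and vehicle MOLM-13 arrays did not overlap in it (2.10 to 2.84 against 0.954 to 1.15). RNA quality as the whole cause of the changes is therefore not excluded by the count. For the 3506 genes whose call ended, the median size of the log2 fold change went from 0.431 to 0.204 and the median SE from 0.101 to 0.155, so the calls ended through both. Whether RNA quality or the inhibitor moved these genes cannot be told apart, since the covariate and the treatment go together in this line. A rise in cell damage under the inhibitor was not tested and stays open as a biological source of the wider difference.

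The effect of the inhibitor differed between days or lines, by its own test, for 1644 genes from day 2 to day 4, 4343 from day 2 to day 6, 2824 from day 4 to day 6 and 5709 between the lines. In 100 splits of the arrays drawn at random within each day or line, 11, 9 and 10 gave as many genes as the real split for the 3 differences between days, with highest counts of 3784, 5519 and 5490 among the others. Of those other splits, 10, 8 and 9 kept the arrays of 1 day as labelled and mixed only the other day, and with both days mixed the highest counts were 1, 2 and 1. For the difference between lines only the real split gave as many genes (1 of 100, highest other 5391), and with both lines mixed the highest count was 3. Splits that keep 1 day or line as labelled keep its effect, and those that mix both remove it, so chance is not excluded by these counts for any of the 4 differences. For each treatment comparison and for the vehicle cultures over time, the 10 splits of 3 against 3 arrays are too few for a share under 0.05. The real counts and the highest of the other splits were 1372 and 2 on day 2, 5068 and 1 on day 4, 6800 and 4 on day 6, 7214 and 10 in MOLM-13 cells, and 123 and 1 in vehicle cultures.

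From day 2 to day 6 the effect also differed for 9 gene lists, given as medians. Granule genes moved by 0.52 (adjusted p = 0.00451, and 0.114 with an estimated correlation), neutrophil genes by 0.47 (0.0462, and 0.116 with an estimated correlation) and MHC class II genes by 1.92 (1.56e-08). Cell cycle genes moved by -0.78 (2.54e-22), MYC and ribosome biogenesis genes by -0.0848 (0.0311, and 0.249 with an estimated correlation) and p53 targets by -0.52 (0.00166). Sterol genes moved by -0.96 (5.12e-09), stress genes by -0.25 (0.028, and 0.504 with an estimated correlation) and S-adenosylmethionine cycle genes by -0.26 (0.0292, and 0.0818 with an estimated correlation).

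Between MOLM-13 and MV4-11 cells 8 lists differed by their median. MLL-fusion targets differed by -0.50 (adjusted p = 0.0391), monocyte and macrophage genes by 0.64 (0.00101) and neutrophil genes by 0.54 (0.0243), each with adjusted p = 0.0818 with an estimated correlation. MHC class II genes differed by -2.65 (1.12e-06), cell cycle genes by 0.61 (3.43e-11) and p53 targets by 0.43 (0.0124). Sterol genes differed by 0.71 (0.000195, and 0.135 with an estimated correlation) and inflammatory genes by 1.01 (0.00166, and 0.158 with an estimated correlation).

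Single genes whose effect became more positive from day 2 to day 4 were TSPOAP1 (4.08), GASK1B (3.91), ZNF366 (3.72), HLA-DPB1 (3.31) and SLC40A1 (3.23). It became more negative for CXCL10 (-6.05), IFIT1 (-5.61), IFIT3 (-4.63), KCNE1 (-4.63) and IFI44 (-4.42), and with the day 2 and day 6 vehicle arrays in place of those of day 4 these 5 stood at -0.40, -0.71, -0.54, -0.94 and -0.39, none called. The call of IFIT3 (adjusted p = 0.0447) also ended without any 1 of 11 of its 12 arrays, all but vehicle day 2 replicate 2 (adjusted p from 0.0515 to 0.132). From day 2 to day 6 the effect became more positive for ZNF366 (5.63), GASK1B (5.21), ALOX5 (4.85), GPAT3 (4.71) and CRISPLD2 (4.61) and more negative for EGR1 (-3.38), IL4I1 (-3.37), AKR1C2 (-3.06), DHCR7 (-3.01) and MIR210HG (-2.83).

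From day 4 to day 6 the effect became more positive for HMOX1 (5.55), CXCL10 (5.39), HES1 (4.66), IFIT1 (4.19) and MX1 (4.16) and more negative for APOL4 (-2.28), AP1S3 (-2.15), GK6P (-1.88), GTF2I (-1.80) and PURPL (-1.78). With the other vehicle arrays CXCL10, IFIT1 and MX1 stood at -0.25, -0.71 and -0.35, and HMOX1 at 2.33. IFIT1 (adjusted p = 0.0266) also lost its call without vehicle day 4 replicate 3 (adjusted p = 0.0589), vehicle day 6 replicate 2 (0.0805) or vehicle day 6 replicate 3 (0.0786). With no filter another probe set stood for HES1 and gave 0.35, and with the 3' to 5' covariate APOL4 had adjusted p = 0.0873. Between the lines the effect was more positive in MOLM-13 cells for NAV3 (6.07), ANKRD22 (5.97), ITGB2-AS1 (5.61), ZEB1 (5.42) and SIGLEC16 (4.94), and more negative for DYNC1I1 (-6.58), ANXA2R (-5.98), GASK1B (-5.84), ROBO1 (-5.71) and HLA-DPB1 (-5.66).

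Outside the genes analysed, probe sets with no gene or several genes listed also differed between treated and vehicle cultures. Of 4528 such probe sets, 447 were called on day 2 (131 higher and 316 lower), 1532 on day 4 (693 and 839), 2226 on day 6 (1135 and 1091) and 2714 in MOLM-13 cells (1657 and 1057).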

How the results depend on the processing

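The day 2 and day 6 vehicle arrays in place of those of day 4 and the 3' to 5' difference as a covariate were tests chosen after the data were seen. Of 377 values of counts and correlations under an alternative, 338 stayed within 1.5 times or within their spread. Part of these could not move. Correlations do not change with a common median, the replicate block, the variance prior or only the arrays of the comparison. Those without an array were set against a spread taken from the same fits. Of 1449 values of gene lists, 1360 kept their direction and side of the threshold, 31 were no longer called, 55 became called and 3 reversed. Of 7265 values of named genes, 6919 kept both, 238 were no longer called, 57 became called and 51 reversed. A stricter filter, quantile normalization again, a common median, the mean of probe sets, no filter and a variance prior with trend moved no total count by over 1.5 times. With a common median the 2123 genes more positive in MOLM-13 than in MV4-11 cells became 3201, and the balance of higher and lower genes turned on days 4 and 6, in MOLM-13 cells, between lines and from days 2 and 4 to day 6. It also turned on day 6 and from days 2 and 4 to day 6 with the mean of probe sets, and in MOLM-13 cells with quantile normalization again. Quantile normalization and the stricter filter gave 434 and 410 gene values, since genes left the filter. The values showed little pairing by replicate number. Of 12 pairs of a treated and a vehicle array 0 had a correlation over 0.1 (from -0.261 to 0.0961), and 2 treated arrays correlated best with their own number. The labels do not state whether a number marks cultures set up together. As a block the replicate numbers moved no count by over 1.5 times, left 84 of 84 list tests and 436 of 438 gene tests on their side of the threshold, and gave 1372 genes as 1269 on day 2. Of the exceptions, CST7 on day 2 became called and IFIT3 from day 2 to day 4 was no longer called (adjusted p = 0.0794). The signal over background limits genes near the lowest value, whose changes depend on the background adjustment. Of these alternatives, the lists added later were run only with an estimated correlation and with the other vehicle arrays, and of their genes only MYC and EGR1 were run, as genes named by the rule.

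With every probe set tested, the counts were 2198, 9553, 14595 and 15902 in the treatment comparisons of days 2, 4 and 6 and of MOLM-13 cells, 9222 from day 2 to day 6, 5951 from day 4 to day 6, 11730 between lines and 199 in vehicle cultures, since more features were counted. With a 2-fold minimum they were 143, 768, 1281, 1400, then 375, 770 and 371 between days, 1469 between lines and 6 in vehicle cultures, since fewer genes pass it. When only the arrays of the comparison were fitted, 4 genes were called in vehicle cultures. With the other vehicle arrays 3540 genes differed from day 2 to day 4, where the day 2 vehicle arrays enter both days and partly cancel, and r of days 4 and 6 was 0.91. These 2 comparisons then share the day 6 vehicle arrays, which gave r = 0.294 in simulated unchanged groups, so part of that r may come from them (covariance 0.400, and 0.00471 in simulated groups). With the covariate the counts were 4339 in MOLM-13 cells, 1497 from day 4 to day 6 and 214 in vehicle cultures, the overlap of the lines was 2286 and their r was 0.40. With an estimated correlation 7, 4, 5 and 4 lists were called in place of 11, 9, 10 and 8, and with fry, which asks only whether a list moves one way, 21, 19 and 19 on days 4 and 6 and in MOLM-13 cells.

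Leaving out each array in turn gave 909 to 981 genes on day 2 (909 without vehicle replicate 1), 4453 to 4703 on day 4, 6265 to 6581 on day 6 and 6647 to 7000 in MOLM-13 cells. The differences between days ranged over 1295 to 1506, 3817 to 4478 and 2108 to 3164, that between lines over 5274 to 6193, and the vehicle count over 28 to 366 (without vehicle day 6 replicates 1 and 3). Lists called ranged over 10 to 11, 9 to 10, 10 to 11 and 8 to 9. The overlaps ranged over 821 to 1512 (days 2 and 6), 3517 to 4221 (days 4 and 6) and 3597 to 3880 (lines), and r over 0.67 to 0.72, 0.75 to 0.81 and 0.41 to 0.46. Of 2868 gene values without an array, 90 were no longer called and 6 became called.

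Some results reversed, and the cause was not tested. As the mean of probe sets, SOX4 was 0.60, TNFRSF10B -0.0836 and POLH -0.32 in MOLM-13 cells. With the other vehicle arrays the interferon list was 0.0516, NOLC1 -0.0400 and CD24 0.0678 on day 4, and CXCL10 -0.25, IFIT1 -0.71 and MX1 -0.35 from day 4 to day 6. With the covariate HHEX was 0.0338, SOX4 0.0235, CD24 -0.15 and EPOR 0.83 in MOLM-13 cells. By fry's direction the stem list on day 6 (median -0.0619) and the p53 list in MOLM-13 cells (median 3.47e-05) differed from camera's.

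Other probe sets of a gene also reversed, 39 of 369. On day 2 MSI2 was -0.15, BAD 0.0308 and 0.12, and TFRC 0.18. On day 4 KMT2A was 0.0345, 0.0741 and 0.74, PSIP1 -0.23, RRP12 0.0689 and 0.0197, NOLC1 -0.0778, and IDI1 0.13 and 0.0894. On day 6 KMT2A was 0.44 and 0.15, CDK9 0.51, MSI2 -0.26 and -0.11, XAF1 -0.76, and IDI1 0.39 and 0.0680. In MOLM-13 cells DOT1L was 0.51, SOX4 0.64, 1.17 and 0.92, MS4A3 -0.35, CD74 -0.0452, BCL2L11 -0.13 and -0.32, CFLAR -0.39, and TNFRSF10B -0.44 and -0.24. There POLH was -1.61 and -0.72, XAF1 -0.51, SQLE 0.45, IDI1 0.35 and 0.0213, and CD24 -1.22. The cause of these was not tested.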

Other observations

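The tests of ERK output genes in this part were chosen after values of some of those genes had been seen, as were the tests of lists with other vehicle arrays, while those of STAT5 output and hypoxia genes were not, and the genes named as examples here were chosen after their values were seen.

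Genes induced by ERK or STAT5 and hypoxia genes were tested in lists other than the fixed ones. The lists were not run with the 3' to 5' difference of each array as a covariate. On day 6 that difference was wider in treated than in vehicle arrays of both lines, so a part played by RNA quality is not excluded there. In MV4-11 cells on day 6 the phosphatase DUSP5, induced by ERK signalling, fell by 2.54 ± 0.18, and the ERK-responsive transcription factor ETV5 fell by 0.99 ± 0.15. The glucose transporters SLC2A3 and SLC2A1 fell, at -2.37 ± 0.23 and -0.95 ± 0.07, as did BNIP3, a regulator of mitophagy, at -1.74 ± 0.17. In MOLM-13 cells BNIP3 fell by 1.72 ± 0.17, and SOCS2, a feedback inhibitor induced by STAT5, fell by 3.20 ± 0.05. The STAT5 targets PIM1 and CISH were at -1.35 ± 0.11 and -0.90 ± 0.07 there. DUSP5 was at -0.63 ± 0.18 in MOLM-13 cells, but DUSP6, another ERK-induced phosphatase, rose by 1.44 ± 0.10 there and fell by 0.52 ± 0.10 in MV4-11 cells.

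A hypothesis is that ERK output was lower under the inhibitor. In MV4-11 cells on day 6, 12 of 14 ERK output genes fell and 0 rose (median -1.12, adjusted p = 9.12e-06 over 12 list tests, and 0.00737 with an estimated correlation). The list was tested after values of some of its genes had been seen. These values and those of the other days therefore go with the hypothesis but are not an independent test of it. In MOLM-13 cells 4 of 14 rose and 5 fell (median -0.17, adjusted p = 0.745, and 0.791 with an estimated correlation), so the hypothesis stays open for that line. The same list had a median of -0.40 on day 2 and -1.47 on day 4 in MV4-11 cells (adjusted p = 3.05e-05 and 1.52e-08). On day 4 it was at -1.20 with the day 2 and day 6 vehicle arrays in place of those of day 4 (12 of 14 fell, adjusted p = 1.37e-05, and 0.00737 with an estimated correlation).

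Another hypothesis is that STAT5 output was lower. In MOLM-13 cells 7 of 11 STAT5 output genes fell and 1 rose (median -0.90, adjusted p = 0.0205), which goes with the hypothesis, though adjusted p = 0.0563 with an estimated correlation. Treated and vehicle arrays of that line did not overlap in the 3' to 5' difference, which was not tested as a covariate for this list. On day 6 in MV4-11 cells 5 of 11 fell and 1 rose (median -0.29, adjusted p = 0.0537, and 0.11 with an estimated correlation), so the hypothesis stays open there. On days 2 and 4 the list was lower in those cells (medians -0.16 and -0.46, adjusted p = 0.0197 and 0.0173, and 0.0563 with an estimated correlation on both days), and on day 4 it did not pass with the day 2 and day 6 vehicle arrays (median -0.27, adjusted p = 0.0519).

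The last hypothesis is that hypoxia genes were lower. Of 19 such genes, 11 fell and 3 rose in MV4-11 cells on day 6 (median -0.95, adjusted p = 0.0161) and 12 fell and 3 rose in MOLM-13 cells (median -0.70, adjusted p = 0.0323), which is consistent with it. Neither passed with an estimated correlation (adjusted p = 0.459 and 0.506 with an estimated correlation), and cell density, which the labels do not give, was not tested. The 3' to 5' difference, wider in treated arrays of both lines on day 6, was not tested as a covariate for this list. On days 2 and 4 in MV4-11 cells the medians were -0.21 and -0.98 (adjusted p = 0.00258 and 9.92e-08, and 0.378 and 0.11 with an estimated correlation), and the day 4 median was -0.61 with the day 2 and day 6 vehicle arrays (adjusted p = 0.0203, and 0.475 with an estimated correlation).

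The day 4 vehicle cultures differed from the day 2 and day 6 vehicle cultures in 3140 genes (1471 higher and 1669 lower), 163 of them at least 2-fold. Besides the 22 of 22 interferon-stimulated genes, 12 of 22 monocyte and macrophage genes, 9 of 14 inflammatory genes, 13 of 23 stress genes and 12 of 18 sterol genes were higher. In the same cultures 25 of 40 cell cycle genes and 12 of 21 MYC and ribosome biogenesis genes were lower. Within groups, 2847 of 10971 genes were called for the 3' to 5' difference of their array. That difference varied mostly in treated MV4-11 cells on day 6 (SD 0.616) and in treated MOLM-13 cells (SD 0.381). In the other groups the SD was 0.00808 to 0.11. The calls therefore rest mostly on the arrays of those 2 treated groups, and whether RNA quality moved these genes was not tested.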
